A study of Mus musculus with 6 samples.

How the data were processed

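Total RNA of mouse forebrain at E14.5 was isolated with on-column DNase digestion and made into libraries with a TruSeq RNA v2 kit, per the labels' protocols. This kit marks no strand, so reads of overlapping genes on opposite strands cannot be told apart; of the 26 genes named for their own change, 10 overlap another annotated gene and 2 (Chtf18 and Srd5a1) overlap a protein-coding one. The submitters' processing notes name TopHat2 2.0.9, HTSeq 0.5.4p5, edgeR 3.4.2 and the mm10 (GRCm38) build, without their order. The deposited count table holds estimated counts per gene and library that the authors did not scale between libraries. Between 22.7% and 24.9% of its values are not exactly whole numbers, with no tolerance allowed, which a counter of whole reads would not give, so the tool that made this table is not given in the sources used here. The authors' deposited comparison table holds log2 fold changes and mean log2 CPM, the p-value and its FDR, and a likelihood-ratio score for each gene, as an edgeR likelihood-ratio test gives. It lists genes with an FDR up to 0.0994, and its model and filter are not given in the sources used here.

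The count table has 34866 rows. Gene identifiers were matched without their version to the symbols of GENCODE M21 (GRCm38), and 99.19% matched, with 284 unmatched. Long non-coding RNAs are nearly absent from the table, with 20 lincRNA and antisense rows, and Xist has no row. Estimated counts were rounded to whole numbers before any count test. Total estimated counts were 23915091, 22819772 and 24490232 in control replicates 1 to 3 and 25999747, 20775429 and 22180229 in mutant replicates 1 to 3. At this depth the biological coefficient of variation was 12.3%, and the median standard error of a log2 fold change was 0.125. Chi-square statistics between replicates of a group were 4.81 to 29.3 per gene, so no 2 replicates of a group were copies of each other.

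Groups were taken from the Sap130 genotype in the labels. Replicate numbers follow accession order and pair nothing. The fixed design compared mutant with control over all 6 libraries using edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total count 15), TMM factors, robust quasi-likelihood fit and Benjamini-Hochberg adjustment at an FDR of 0.05. CPM values use TMM-scaled library sizes, and log2 CPM values a prior count of 2. Of 41 gene lists written, 40 with at least 5 tested members were tested with limma 3.58.1 (camera with a preset correlation of 0.01, camera with an estimated correlation, and fry), and the sex-linked list served only as a check. The sex-linked list's median log2 CPM minus the control mean was -4.16 in control replicate 2 and -2.66 in mutant replicate 2. It was 1.75 and 2.41 in control replicates 1 and 3, and 2.54 and 2.325 in mutant replicates 1 and 3. Each group thus held 1 library with low values. The rule for named genes took Sap130, the 12 largest rises and 12 largest falls among called genes with a mean of at least 1 CPM and no overlap between groups, and up to 4 members by p, with called members, in each described list. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were given. Of the genes this rule names, 2 are not reported here. The groups, tests, lists, naming rule and first set of other settings were fixed before the data were examined.

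The scripts were tested on simulated data for the mutant against control comparison, with 10 draws of counts for the 15216 genes from the real means, library sizes and dispersions. Of 100 genes changed by 1.5-fold in each draw 53.6% were called, and of 100 changed by 2-fold 77.1%. False calls made up 7.8% of all calls over the draws (2.96% to 13.1% in single draws), above the nominal FDR of 0.05, and 9.64% with the title-number block. Every one of 10 simulated lists of 20 genes raised 1.3-fold was found, and 2.2% of 2000 unchanged lists had a p under 0.05. Simulated genes varied independently of each other, while estimated correlations within the real lists reached 0.665. The list rates of the simulation therefore do not carry over to the real lists. The draws also held no difference between title numbers, with mean calls per draw of 146.1 without the block and 148.4 with it. The real libraries gave 21 and 116, so the simulated shares of genes called and of false calls may not carry over either.

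Alternatives covered scaling (RLE, upper quartile, totals), tests (DESeq2 1.42.0, edgeR's exact test, limma-voom), filters, thresholds of 0.01 and 0.1, a minimum 1.2-fold change, the title number as a block, SPF-552 alone, and leaving out each library. Added after the data were examined were a Y-linked covariate, the diencephalon list's score in each library as a covariate, edgeR's likelihood-ratio test, a per-library offset for exon length, that offset with the block, and upper-quartile factors for the gene lists. Figures were drawn with matplotlib 3.10.9.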

Results

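RNA was sequenced from the forebrain of mouse embryos at E14.5 (embryonic day), when radial glia of the dorsal telencephalon are producing deep-layer and, increasingly, upper-layer cortical neurons. Sap130 encodes a subunit of the Sin3 histone deacetylase co-repressor complex. The Emx1-cre driver recombines floxed alleles in the lineage of the dorsal telencephalon, which gives rise to the excitatory neurons and glia of the cortex and hippocampus. The 6 libraries comprised 3 labelled mutant (1 floxed and 1 null Sap130 allele with Emx1-cre) and 3 controls (1 floxed and 1 wild-type allele with Emx1-cre). A control thus keeps 1 working allele inside the lineage, and a mutant keeps 1 outside it and none inside. The libraries held 20775429 to 25999747 estimated counts, and 15216 genes had enough counts to be tested. The series describes 3 conditional knockouts and 3 littermate controls, without saying which animals share a litter. Sample titles begin with SPF-539 (2 libraries, 1 of each group) or SPF-552 (4 libraries, 2 of each group). The first principal component of the libraries, with 29.5% of the variance, separated these title numbers. The count of genes is therefore also given with the title number as a block, and values within each title number are given for Sap130 and the diencephalon list.

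The targeted gene was examined first, as a check of the labels. Sap130 (ENSMUSG00000024260, GRCm38 chromosome 18, 31634371 to 31723061, plus strand) was higher in the libraries labelled mutant, which goes against a loss of the gene. Its level was 84.0 ± 1.10 CPM (SD, n = 3) in controls and 128.6 ± 7.85 CPM (SD, n = 3) in the libraries labelled mutant, a 1.53-fold difference. The log2 fold change was 0.61 with a standard error of 0.076 and an adjusted p of 0.0116 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Every library labelled mutant (124.05 CPM or more) lay above every control (84.904 CPM or less). The exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 allow. Within SPF-539 the log2 ratio was 0.73, and within SPF-552 it was 0.55. The counts are summed over the whole gene, so transcripts that lack the floxed part but keep other exons are counted too, and the sources used here do not say which exons are floxed. All directions below are therefore those of the libraries as labelled. The call was lost on leaving out control replicate 1, 2 or 3 or mutant replicate 2 (adjusted p = 0.0976, 0.111, 0.0798 and 0.0689), with log2 fold changes of 0.61, 0.62, 0.62 and 0.64 in these 4 fits.

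**Figure D1:**
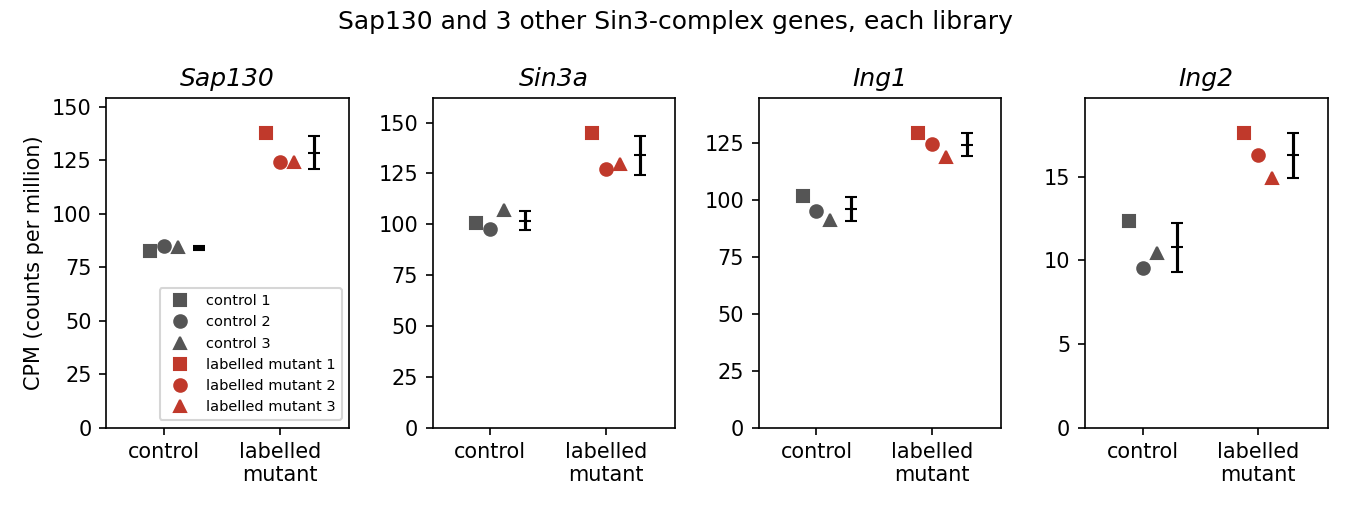
CPM (linear axis from 0) of Sap130, Sin3a, Ing1 and Ing2 in each of the 3 control and 3 labelled mutant libraries, with the group mean and SD as a black bar beside the points. For each of the 4 genes all labelled mutant libraries lie above all controls, with Sap130 means of 84.0 and 128.6 CPM.

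The main comparison asked which genes differ in the embryonic forebrain when Sap130 is targeted in the cortical lineage. Neurod6 and Neurod2, bHLH factors of differentiating excitatory neurons, were lower in the libraries labelled mutant and fell from 287.0 ± 1.62 to 153.6 ± 18.98 CPM and from 307.2 ± 13.2 to 182.7 ± 22.3 CPM (SD, n = 3 each). Eomes, which marks intermediate progenitors, fell from 179.8 ± 5.41 to 114.2 ± 19.6 CPM. In all, 21 of the 15216 genes passed an FDR of 0.05, 4 higher and 17 lower, by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 the balance was the other way, with 795 genes higher and 666 lower.

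Among the genes that fell, Rlbp1, which encodes a retinaldehyde-binding protein, had the smallest adjusted p (0.000151), at 43.7 ± 1.56 CPM in controls and 16.5 ± 0.946 CPM in the libraries labelled mutant (SD, n = 3). The largest falls in log2 fold change belonged to Ankrd63 (-2.15), the tight-junction gene Cldn3 (-1.9985) and Sypl2 (-1.88), whose control means lay between 2.90 and 4.44 CPM. Cbs, encoding cystathionine beta-synthase, had a log2 fold change of -1.29. Nxph3, a neurexophilin of deep cortical layers, had -1.28, and the brain proteoglycan gene Bcan had -1.08. Mpped1 and the HLH regulator Id2 followed at -0.86 and -0.84. Neurod6 (-0.90) and Neurod2 (-0.75) were also among the 12 largest falls. Smaller falls that passed were those of Plekhf2 (-0.68), Eomes (-0.65), Nfatc4 (-0.65), the immediate early gene Ier5 (-0.59) and Aldoc (-0.59), a glycolytic enzyme of radial glia.

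The 4 genes that rose were Prr15 (log2 fold change 1.39), Zfhx3 (0.67), Sap130 (0.61) and Slit2 (0.51). Zfhx3, a homeobox factor of the ventral telencephalon, went from 84.4 ± 7.79 to 134.4 ± 7.57 CPM, and Slit2, a repulsive axon guidance cue, from 59.4 ± 4.17 to 84.7 ± 1.09 CPM (SD, n = 3). The next 5 genes by p did not pass. They were Chtf18 (0.68, adjusted p = 0.0565), the imprinted gene Peg3 (0.50, adjusted p = 0.0584), Pcdh19 (0.52, adjusted p = 0.059), Larp1b (0.79, adjusted p = 0.0897) and Srd5a1 (0.63, adjusted p = 0.0976) by edgeR's quasi-likelihood test. With the title number as a block all 5 passed the same test (adjusted p = 0.0123, 0.0179, 0.0217, 0.0384 and 0.0217, in this order). For all 21 called genes the 3 control values and the 3 labelled mutant values did not overlap, against 16.7% of all tested genes and 10% by chance. Calling in the same comparison favours genes without overlap, so this is no separate support for the calls.

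The count of genes depended on 1 library and on the title number. With the title number as a block 116 genes passed, 38 higher and 78 lower, including all 21 with the same sign, and within SPF-552 alone (2 against 2) 564 passed, 237 higher and 327 lower. SPF-539 is 1 library against 1 and has no test. Without mutant replicate 1 the count was 330; leaving out any other single library gave 3 to 9.

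**Figure D2:**
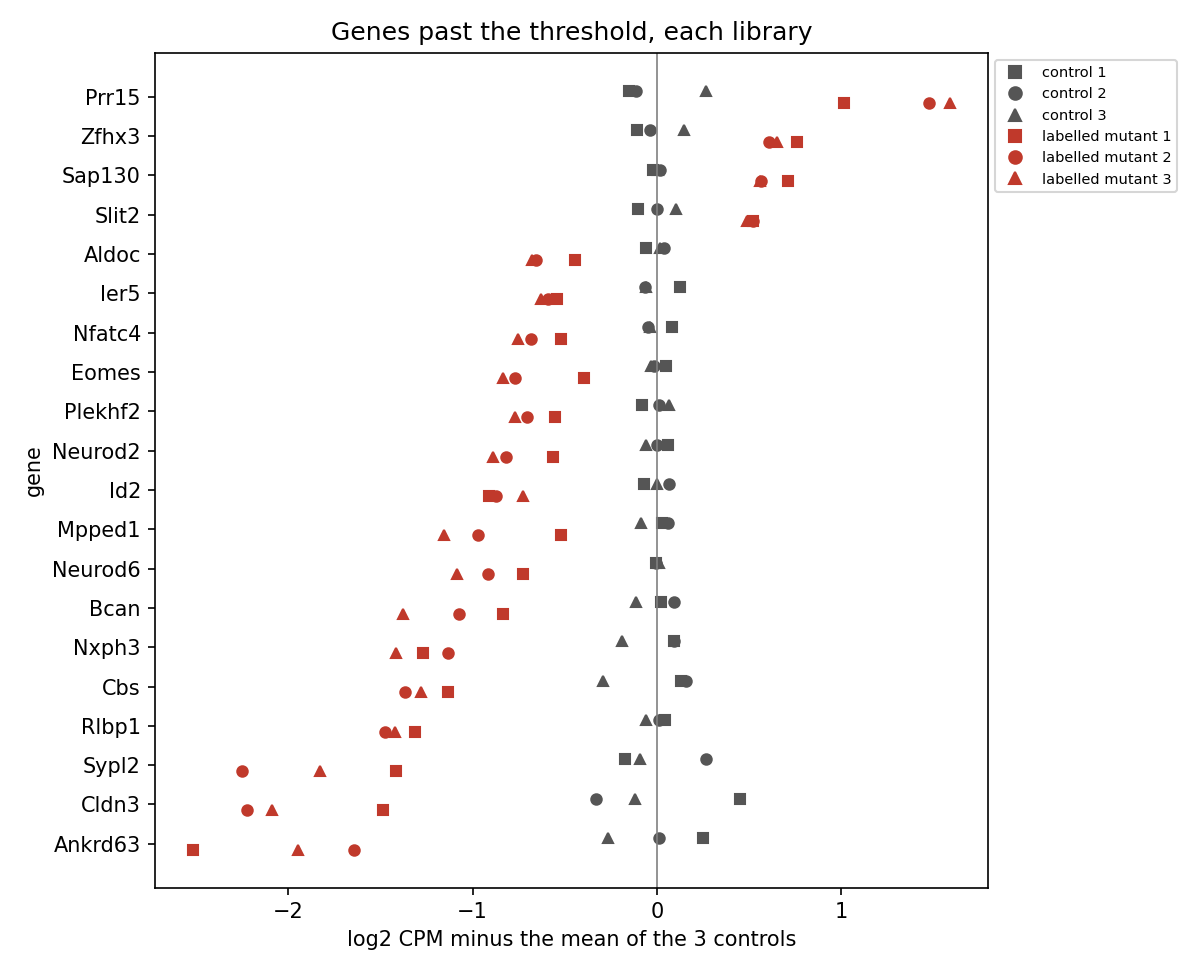
Log2 CPM of each library minus the mean of the 3 controls for 20 of the genes that passed, ordered by fold change, with 1 point per library and symbols for the replicate. Control points scatter around 0, and the 3 labelled mutant points lie to the right for 4 genes and to the left for 16.

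Gene lists fixed before the data were examined were then compared with all other genes by camera with a preset correlation of 0.01. Of the 40 lists tested, 16 passed, 11 higher and 5 lower. None passed with a correlation estimated for each list (smallest adjusted p = 0.441) or with fry's directional test (smallest adjusted p = 0.0558), and 18 passed fry's test of change in either direction.

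Lists of deep-layer and upper-layer cortical neurons and of intermediate progenitors were lower. Of 13 deep-layer neuron genes 1 fell over all genes tested and, adjusted over the list alone, 6 fell and 1 rose (median log2 fold change -0.25, camera adjusted p = 0.000504; adjusted p = 0.441 with an estimated correlation). Without mutant replicate 3 the median of this list was -0.13, and the call was kept in all 6 fits that left out 1 library. Nxph3 led this list. Sox5 (-0.50), Crym (-0.80), Fezf2 (-0.37) and Tbr1 (-0.27), factors and markers of subcortically projecting neurons, fell when adjusted over the list alone, while Foxp2 rose at 0.35. Of 16 intermediate progenitor genes Eomes fell over all genes and, adjusted over the list alone, 5 fell (median -0.17, camera adjusted p = 0.000504; adjusted p = 0.441 with an estimated correlation). These included the neurogenic factors Insm1 (-0.39) and Neurog2 (-0.31) and the somatostatin receptor gene Sstr2 (-0.56). The list stood at -0.41 in mutant replicate 1 and at -0.12 and -0.13 in mutant replicates 2 and 3, and without mutant replicate 1 its median was -0.11, still past the threshold. Of 14 upper-layer genes 1 fell over all genes and 2 fell adjusted over the list alone, Bhlhe22 (-0.56) among them (median -0.07, camera adjusted p = 0.0301; adjusted p = 0.722 with an estimated correlation). The upper-layer call was lost without control replicate 2 or 3 or mutant replicate 2 or 3, with a highest adjusted p of 0.182. Its median went from -0.19 without mutant replicate 1, where the list stood at 0.02, to -0.04 without control replicate 3 or mutant replicate 3, and was -0.13 without control replicate 1.

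The ganglionic eminence list, the Cajal-Retzius and cortical hem list and the diencephalon list were higher. For the 28 ganglionic eminence and inhibitory neuron genes the median was 0.22 (camera adjusted p = 2.84e-05; adjusted p = 0.441 with an estimated correlation). Zfhx3 rose over all genes, and 4 members rose adjusted over the list alone, among them Zfhx3, Sp8 (0.35) and Sp9 (0.35), factors of interneuron and striatal development. The 20 Cajal-Retzius and cortical hem genes had a median of 0.29 (camera adjusted p = 2.84e-05; adjusted p = 0.441 with an estimated correlation), and Ebf2 (0.72), Ebf3 (0.70) and the hem gene Wnt8b (0.77) rose adjusted over the list alone. In log2 CPM minus the control mean, Ebf3 stood at 0.34 in mutant replicate 1, no higher than the 0.36 of control replicate 1. It stood at 0.96 and 0.79 in mutant replicates 2 and 3. Wnt8b stood at 0.21, 0.84 and 1.13 and Ebf2 at 0.41, 0.81 and 0.90 in mutant replicates 1 to 3. The 21 tested genes of the diencephalon and other brain regions had a median of 0.39 (camera adjusted p = 2.45e-06; adjusted p = 0.534 with an estimated correlation). Sim1 (0.61) and the thalamic factor Tcf7l2 (0.39) rose adjusted over the list alone, and no member passed over all genes.

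The list medians of single libraries differed between title numbers. The diencephalon list stood at 0.50 and 0.56 above the control mean in mutant replicates 2 and 3, but at 0.08 in mutant replicate 1, below the 0.19 of control replicate 1. The mutant minus control difference was thus -0.104 in SPF-539 and 0.589 in SPF-552. The ganglionic eminence list lay at 0.16, 0.17 and 0.27 in the libraries labelled mutant and at -0.08, 0.04 and 0.07 in controls. The Cajal-Retzius and cortical hem list lay at 0.19, 0.32 and 0.33 in the libraries labelled mutant and at 0.10, -0.04 and 0.004 in controls. Markers of choroid plexus, endothelial cells, meninges and microglia had medians of -0.02, -0.08, 0.02 and -0.03, and none of these 4 lists passed.

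**Figure D3:**
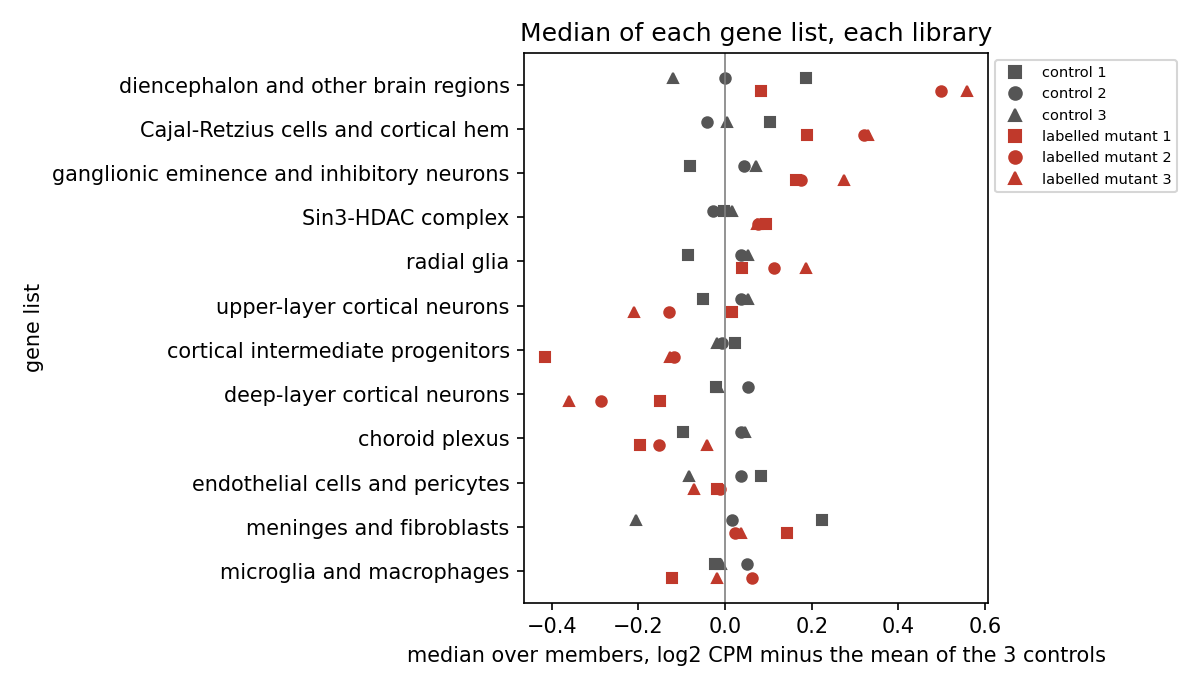
Median over the members of 12 gene lists of log2 CPM minus the mean of the 3 controls, with 1 point per library. The deep-layer list lies below every control in all 3 labelled mutant libraries, and the diencephalon list is high in mutant replicates 2 and 3 but at 0.08 in mutant replicate 1.

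Genes of the Sin3 histone deacetylase complex were higher as a list. Of 24 members Sap130 rose over all genes and, adjusted over the list alone, Sap130, Sin3a, Ing1 and Ing2 rose (median 0.06, camera adjusted p = 0.00732; adjusted p = 0.441 with an estimated correlation). Sin3a, the scaffold of the complex, went from 101.8 ± 4.68 to 133.9 ± 9.46 CPM. Ing1 and Ing2, chromatin-reading subunits, went from 96.1 ± 5.41 to 124.4 ± 5.10 CPM and from 10.8 ± 1.46 to 16.3 ± 1.33 CPM (SD, n = 3). With Sap130 itself left out, fry's directional p for the 23 others was 0.00516, and 0.00983 with the title-number block. Of the 24 members 7 had a log2 fold change below 0. The list's median was 0.03 without control replicate 1 or 2, with the call kept in both fits.

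The authors' deposited table lists 369 genes at an FDR under 0.1, 167 higher and 202 lower. Of these, 353 have a row in the count table and 352 had the same sign here, with a correlation of log2 fold changes of 0.994 across genes, which are not independent replicates. The authors' deposited table gives Sap130 a log2 fold change of 0.61 as well. That table is the authors' own comparison of the same 2 groups and lists only genes under its FDR limit. Close agreement with it is therefore no independent support and would not reveal an exchange of labels. At an FDR under 0.05 it holds 262 genes, with a likelihood-ratio score, against 21 here by the quasi-likelihood test. With edgeR's likelihood-ratio test, added after the data were examined, 160 genes passed here, and 141 of these are among the 262. Of the 253 tested here 247 had an unadjusted p under 0.05 by the quasi-likelihood test. Of the 21 genes called here 20 are in the authors' table under 0.05. Ankrd63, with the largest fall here and 0.43 to 0.86 CPM in the libraries labelled mutant, is not listed there.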

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

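The tests of Sap130, the list of Sin3-complex genes, the cortical lists, exon length, the title-number block and the interaction term in this part were chosen after the result was seen, although the scaling, block and left-out-library fits that some of them read were fixed beforehand; the diencephalon covariate and the other splits of the libraries were set down before their result.

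An edgeR interaction term of group and title number, adjusted over the 26 named genes, passed for Mpped1 and Eomes. The fall in SPF-552 exceeded that in SPF-539 by a log2 difference of -0.498 for Mpped1 and -0.3347 for Eomes (adjusted p = 0.0101 and 0.0306), and each gene was lower in 3 of 3 labelled mutant libraries. SPF-539 holds 1 library of each group, so this term rests on control replicate 1 and mutant replicate 1, assumes that they vary as the SPF-552 libraries do, and does not separate these 2 libraries from the title number. Over all genes 1322 interaction calls were made, against 0 to 6 in the simulated draws, so that assumption may not hold and no difference between the title numbers is read from it. With the exon-length offset 211 were made and Neurod6, Neurod2 and Aldoc passed as well as Mpped1 and Eomes.

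The authors' deposited table holds a signal in 16 genes that have no row in the count table, 9 of them at an FDR under 0.05. The authors' deposited table gives Gm29260 a log2 fold change of -1.05 and Gm42047 -0.66.

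Sap130 was higher in the libraries labelled mutant, where the genotype predicts less. Scaling is argued against as the cause of the rise of Sap130 relative to other genes, since a scaling factor shifts all genes of a library alike. Medians over all genes were -0.0136 to 0.00281 with 4 sets of scaling factors, library totals among them. The lowest Sap130 log2 fold change over these sets was 0.6009. The 4 sets hardly differ, so they do not test a shift of all genes in absolute level. A change of the region is argued against by the median of 0.0137 over the 15 tested genes within 1 Mb, of which none passed. An exchange of the 2 groups' labels as a whole cannot be told apart from transcript of the altered alleles. The ratio of labelled control to labelled mutant was 0.653. An exchange allows at most 0.5 if altered alleles give no transcript and each intact allele keeps its usual output. Gene-level counts do not show which exons were read, so remaining transcript could raise the ratio. A higher output of an intact allele could raise it too and was not tested. A biological hypothesis is that expression of the complex rises together when a subunit is altered, and limma's fry gave a directional p of 0.00516 for the 23 others. This rests on few members, as Sin3a, Ing1 and Ing2 rose when adjusted over these 23, 7 of the 24 members lay below 0, and the whole list had an adjusted directional p of 0.0558. An exchange of labels would turn every direction given for the libraries labelled mutant.

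By camera with a preset correlation, lists of deep-layer and upper-layer cortical neurons and of intermediate progenitors were lower. Lists of the ganglionic eminence, of Cajal-Retzius cells and the cortical hem, and of the diencephalon and other brain regions were higher. None of these 6 passed camera with an estimated correlation (adjusted p = 0.441 to 0.722). The upper-layer call was also lost in 4 of the 6 fits that left out 1 library. Replacement of cortical by neighbouring brain tissue as the whole cause cannot be told apart from a change within the cortical lineage. A set of 7 cortex-restricted genes fell unequally (Neurod6 -0.90, Emx1 -0.24; a heterogeneity p of 1.4e-08 by Cochran's Q, which takes edgeR's standard errors as independent), but it was picked after its values were seen, holds called genes of the pattern and leaves out Emx2 (0.18), so it excludes nothing. For fewer cortical cells against all other types alike, the ganglionic eminence list was compared with 73 choroid plexus, vascular, meningeal and microglial genes. The list exceeded them by 0.225 (standard error 0.0758) more in the libraries labelled mutant. Values were 0.224 to 0.226 in labelled mutants and -0.127 to 0.135 in controls, so the standard error rests almost wholly on the controls. The list had also already been called higher in these libraries. This comparison therefore does not decide the question, and it says nothing about tissue replacement. The diencephalon score of each library was also used as a covariate. The median log2 fold change of the 17 called lower genes stayed at -0.738 (-0.858 without it). These genes were called in the same libraries and were lower in every labelled mutant library, mutant replicate 1 included. There the score was 0.08, below the 0.19 of control replicate 1. The covariate could therefore take up little of their fall, so this fit does not decide on diencephalic carry-over. In it 323 genes passed, 233 higher and 90 lower, with 15 of the 21. For the rise of the diencephalon list itself, dissection and genotype cannot be told apart, since the difference was -0.104 in SPF-539 and 0.589 in SPF-552, and the genotype stays open as an untested biological explanation.

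The number of called genes rose from 21 to 330 without mutant replicate 1. Deviations of mutant replicate 1 from the mean of all libraries correlated with exon length across genes (Spearman rho 0.375, against -0.256 to -0.0235 in the other 5 libraries). The next strongest was control replicate 1 (-0.256), the other SPF-539 library, with the opposite sign. Deviations from the mean of all libraries cancel for each gene, so a trend in mutant replicate 1 pushes the others the other way. No trend shared by SPF-539 is therefore read from these values. An offset for exon length raised the count to 68, so a length trend may be part of the cause. What gave this trend was not tested. The title number as a block gave 116 genes, and both together 407, so a difference between the title numbers may add to it. With the diencephalon score as a covariate 323 passed, and mutant replicate 1 has a score of 0.08 against 0.50 and 0.56 in the other libraries labelled mutant, so a difference in tissue content stays open too. Mutant replicate 1 is also 1 of only 2 libraries of SPF-539, so a litter or handling difference and a property of this library cannot be separated for the 330. No biological explanation was tested for this pattern.

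Other splits of the 6 libraries bear on chance. The real split called 21 genes and the highest other 5, with 1 of 10 splits reaching 21. For lists the real split called 16 and the highest other 19 (control 1 with mutants 2 and 3), with 3 of 10 splits reaching 16. These splits ignore the title number. The split of controls 1 and 2 with mutant 1, which called 5 genes and 18 lists, has both SPF-539 libraries on the same side. With 10 splits no share under 0.05 is possible.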

How the results depend on the processing

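The Y-linked and diencephalon covariates, likelihood-ratio test, length offsets and upper-quartile factors for lists were chosen after the data were examined; the planned Xist covariate was not run, as Xist has no row in the count table. Against 21 genes (4 higher, 17 lower) the count was 194 with DESeq2 (88 higher, 106 lower), 130 with edgeR's exact test, 11 with limma-voom, 130 with no low-count filter, 116 with the title-number block, 564 in SPF-552 only, 11 with robust fitting off, 4 with a minimum fold of 1.2, 4 at an FDR of 0.01, 56 at 0.1, 11 with the Y-linked covariate, 323 with the diencephalon covariate (233 higher, 90 lower; 15 of the 21 genes shared), 160 with the likelihood-ratio test, 68 with the length offset (19 of the 21 genes shared) and 407 with that offset and the block; the cause was not tested. Leaving out 1 library gave 3 (without mutant replicate 2) to 330 (without mutant replicate 1), and 4 to 9 without another. Calls stayed within 1.5 times with RLE (20), upper quartile (30), totals (30), a stricter filter (20) and no sex-linked genes (21). Against 16 lists, 0 passed with an estimated correlation and 0 with fry, 12 to 17 on leaving out 1 library and 15 to 18 otherwise. The length offset kept 12 of the 16 lists and lost the congenital heart disease, ribosomal, oxidative phosphorylation and G1/S lists; it moved the medians of the Sin3 and upper-layer lists to 0.02 and -0.14 with their calls kept. The ribosomal list had medians from -0.1571 to 0.007571 on leaving out 1 library, reversed without mutant replicate 1 and lost its call without control replicate 1 too (adjusted p = 0.0538). Sap130 kept its direction throughout, from 0.56 to 0.64, with adjusted p from 1.49e-08 to 0.111 over its alternatives. Leaving out 1 library gave a log2 fold change of 0.5623 to 0.6389, and 4 of these 6 fits lost the call with fewer libraries. None of the 20 other called genes reversed in any alternative run for single genes. The sign share against the authors' deposited table was 99.72% in all 5 fits compared. At this depth and with 3 libraries a group 53.6% of simulated 1.5-fold changes were called, in draws without a difference between title numbers. This share may not carry over to the real libraries, and neither depth nor the number of libraries was varied.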

Other observations

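The exon-length offset in this part was chosen after the data were examined. Lists of other pathways and gene sets passed camera as well, in the libraries as labelled. Of 28 p53 pathway genes none passed over all genes, and 4 rose adjusted over the list alone: Sesn2 (0.71), Zmat3 (0.34), Ccng1 (0.39) and Aen (0.31), known targets of p53 (median 0.09, camera adjusted p = 0.029; adjusted p = 0.441 with an estimated correlation). The list stood at 0.10, 0.11 and 0.11 in the libraries labelled mutant and within 0.02 of 0 in all 3 controls, but the call was lost without control replicate 2 or 3 or mutant replicate 2 or 3 (highest adjusted p = 0.0855), and its median ranged from 0.03 without mutant replicate 2 to 0.11 without control replicate 1. Of 27 tested imprinted genes Peg3 (0.50), a paternally expressed zinc-finger gene, rose adjusted over the list alone (median 0.12, camera adjusted p = 0.00918; adjusted p = 0.441 with an estimated correlation), and the call was lost without mutant replicate 3 (median 0.08, adjusted p = 0.0666), with a median of 0.08 without mutant replicate 2 too. Of 27 tested congenital heart disease genes Nr2f2 (0.31) rose adjusted over the list alone (median 0.10, camera adjusted p = 0.00472; adjusted p = 0.698 with an estimated correlation), and the call was lost without mutant replicate 1 (median 0.03, adjusted p = 0.0935) and with the exon-length offset (median 0.02, adjusted p = 0.0984). The heart disease list stood at 0.25 in mutant replicate 1, the library with a trend on exon length (Spearman rho 0.375 across genes), and at 0.01 and 0.08 in mutant replicates 2 and 3.

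Axon guidance genes went both ways. Of 30 members Slit2 rose over all genes and, adjusted over the list alone, Slit2, Netrin-1 gene Ntn1 (0.32) and the commissural receptor gene Robo3 (0.92) rose while Cntn2 (-0.66) and Draxin (-0.30) fell (camera adjusted p = 0.126). Radial glia genes also split: Aldoc fell over all genes, and adjusted over the list alone Aldoc and Dbi (-0.55) fell while Sox21 (0.35) and Nes (0.30) rose (median 0.16, camera adjusted p = 0.0594; adjusted p = 0.698 with an estimated correlation). The radial glia list passed camera with the block (adjusted p = 0.0474) and without control replicate 2 or 3 or mutant replicate 1 (0.0474, 0.027 and 0.0146), and with the exon-length offset (0.041), and had an adjusted p of 0.561 by fry's directional test. Among pan-neuronal genes Neurod6 and Neurod2 fell over all genes and Neurod1 (-0.56) with them adjusted over the list alone (camera adjusted p = 0.0844, and 0.0413 with the exon-length offset).

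Lists of metabolism and growth passed camera but lost the call when certain single libraries were left out. Oxidative phosphorylation (median -0.09) and cytosolic ribosomal genes (median -0.07) stood at -0.29 and -0.27 in mutant replicate 1, and both calls were lost without it (medians -0.02 and 0.01, adjusted p = 0.85 and 0.809). The ribosomal call was also lost without control replicate 1 (adjusted p = 0.0538). Without mutant replicate 2 or 3 the medians were -0.15 and -0.17 for oxidative phosphorylation and -0.12 and -0.16 for the ribosomal list. With an estimated correlation both had an adjusted p = 0.751. The exon-length offset ended both calls and that of G1/S. The G1/S (median 0.10), G2/M (median 0.10) and unfolded protein response (median 0.11) lists had an adjusted p = 0.751, 0.751 and 0.704 with an estimated correlation and lost their call without control replicate 1, mutant replicate 2 or mutant replicate 3, and G1/S also without control replicate 2 (highest adjusted p = 0.984, 0.673 and 0.377). Their medians were 0.01, -0.003 and 0.02 without control replicate 1 and 0.19, 0.21 and 0.19 without mutant replicate 1, and the unfolded protein response list was at 0.19 without control replicate 3 too. Mitochondrially encoded genes had a median of 0.14, with an adjusted p = 0.698 with an estimated correlation, and lost their call without control replicate 1 or mutant replicate 2 (highest adjusted p = 0.177), with a median of 0.06 in either fit. Their median was 0.23, 0.24 and 0.24 without control replicate 2, control replicate 3 or mutant replicate 1. No member of these 6 lists passed, over all genes or adjusted over the list alone.

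Of the 24 lists that did not pass, the smallest camera adjusted p was 0.0594. Of the neuronal genes normally repressed by REST, Cplx1 (-0.53) fell adjusted over the list alone, and the list's median was 0.0075 while its camera direction was lower (adjusted p = 0.9).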
